A study of Homo sapiens with 6 samples.

How the data were processed

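Messenger RNA was measured by sequencing in 6 libraries of OVCAR8, a cell line of high-grade serous ovarian cancer: 3 libraries of the parental line and 3 of a line in which NOS2 was knocked out. Groups were taken from the genotype label of each sample. Per the labels' protocols, total RNA was isolated with a Qiagen RNeasy column kit and libraries were made with a SMARTer mRNA-Seq kit. The labels do not say how NOS2 was disrupted, or whether the knockout line is a single clone. Nothing in them says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be only technical.

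The deposited table holds raw counts per Ensembl gene, 1 column per library, with no normalisation. The genome build was GRCh38 (hg38), per the submitters' processing notes. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Of the 57500 gene identifiers, 56410 were paired with a symbol and 56898 had a position in GENCODE release 29 on GRCh38, from which coordinates and gene types were taken. Because the strand setting is not known, reads of overlapping genes on opposite strands cannot be told apart. Counts of near-identical copies, such as IFITM1 to IFITM3, the HLA genes, HSPA1B and the ribosomal protein genes with their processed pseudogenes, are uncertain in the same way.

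Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16259 genes. Libraries were scaled by TMM, and the quasi-likelihood test with robust dispersions compared knockout with parental libraries without covariates. Adjusted p is the Benjamini-Hochberg value over all tested genes, and a gene was called changed at an adjusted p under 0.05. Levels are CPM, counts scaled to a common total on TMM-scaled library sizes, given as mean ± SD over 3 libraries. A log2 fold change is knockout over parental, with a prior count of 2, and its standard error (SE) is its size divided by the square root of the quasi-likelihood F. Total counts were 28993579 to 33560394 per library, and 3 counts, taken as the detection floor, were 0.0894 to 0.103 CPM. Such limits cover counting error only.

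For NOS2 and VIM a two-sided exact permutation test on CPM was added. With 3 libraries against 3 its smallest possible p is 0.1.

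Before the data were examined, 35 gene lists were fixed. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists covered nitric oxide synthesis, the genes next to NOS2, mesenchymal and epithelial markers, intermediate filaments, Mullerian markers, drug transport, glutathione and NRF2, DNA repair, stem cell markers, apoptosis, p53, NF-kB cytokines, interferon-stimulated genes, antigen presentation, hypoxia and glycolysis, nuclear and mitochondrial respiratory chain genes, ribosomal proteins, the proteasome and stress responses. They further covered S phase, G2 and M phase, cholesterol synthesis, targets of TGF-beta, YAP, WNT, NOTCH and ERK, extracellular matrix, integrins and cadherins, leukocyte, endothelial and fibroblast or mesothelial markers, and immediate early and heat shock genes.

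The genes to be named were also fixed by rule. They were NOS2 and VIM, and the 10 highest and 10 lowest fold changes among changed protein-coding genes with no overlap between groups and a mean of at least 5 CPM in one group. From each list they were up to 4 changed members with the smallest p. Any other gene named was chosen after its values were seen. Some genes that meet the rule are not reported here.

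Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors and library size alone, no count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, the DESeq2 1.42.0 Wald test, limma-voom, and glmTreat. A prior count of 0.5 for the list test and leaving out each library in turn were fixed as well. A GC and length offset per library, and the removal of genes in shifted chromosome regions, were chosen after seeing the data.

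The search along the chromosomes was likewise chosen after seeing the data. It used 13715 genes with a mean of at least 1 CPM, and took the median log2 fold change in windows of 31 neighbouring genes. The limit of 0.212 was the 95th percentile of the largest absolute window median over 1000 shuffles of gene order. A region joined windows past that limit with gaps of up to 5 windows, ran between the central genes of its first and last window, and had to hold at least 20 genes. Genes between a chromosome end and the central gene of the nearest window were therefore counted as outside. This was not the only boundary rule tried. Joining gaps of up to a full window with no minimum size gave 18 regions with 888 genes. Extending regions to the chromosome ends gave 13 regions with 886 genes. The reported rule gave 10 regions with 738 genes, all of which were also in the regions from both other rules.

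The procedure was tested on simulated counts for this comparison, over 16058 genes. Of the 66, 66 and 67 genes changed by 0.25, 0.5 and 1 on the log2 scale, 47.0%, 77.3% and 92.5% were recovered, and 5.88% of calls were false. For the regional search, 0.3 was added to the fitted log2 fold changes of a block of 60 neighbouring genes, and fewer shuffles were used. This block was found as 1 region, and 0 regions were found without it. In the simulation genes varied independently and far fewer were changed than in the data, so these rates may not hold for the data.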

Results

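Gene expression was measured in OVCAR8, a cell line of high-grade serous ovarian cancer, in 3 libraries of the parental line and 3 libraries of a NOS2 knockout line. NOS2 encodes the inducible nitric oxide synthase. Per the title of the series, the study concerns nitric oxide, the stability of the intermediate filament protein vimentin, and resistance to chemotherapy. The comparison therefore asks what differs in the transcriptome between the knockout and the parental line. Total counts were 31048112, 30471974 and 33541849 in the parental libraries and 29973116, 28993579 and 33560394 in the knockout libraries, and 24521 to 24894 genes had at least 1 count. The 10 most abundant genes took 5.74% to 5.91% of the counts. Spearman correlations of log CPM were 0.997 within both groups and 0.990 to 0.991 between them. The first principal component separated the groups and held 60.02% of the variance. Nothing in the labels says that the replicates came from separate cultures, so the p-values may measure only technical spread.

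NOS2 (ENSG00000007171, chromosome 17, 27756766 to 27800499, GRCh38) had 233, 199 and 281 counts in the parental libraries and 183, 190 and 204 in the knockout libraries. Its level was 7.46 ± 0.91 CPM in parental and 6.26 ± 0.27 CPM in knockout cells (SD, n = 3 each). Its log2 fold change was -0.26 (SE 0.10), with an adjusted p of 0.039 by edgeR. The exact permutation test, two-sided, gave p = 0.2. The edgeR call was lost without parental library 1 or 3, or without any of the knockout libraries, and without parental library 3 the log2 fold change was -0.16 with an adjusted p of 0.281. It was also lost with no count filter (adjusted p 0.0542), with limma-voom (0.0543), with DESeq2 (0.122) and with a GC and length offset (0.0653). A transcript can persist when a protein is lost to a frameshift, so its count neither supports nor contradicts the labels of the knockout libraries. Of the 14 tested genes of the list fixed for its neighbourhood, 7 fell and 0 rose, and 8 changed when adjusted over the list alone. Among these, SPAG5 had a log2 fold change of -0.33, PIGS of -0.36, WSB1 of -0.30 and POLDIP2 of -0.25. The list was called by camera (adjusted p = 0.0109), but not with an estimated correlation (adjusted p = 0.436 with an estimated correlation). Without knockout library 3 camera gave an adjusted p of 0.0781.

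VIM, which encodes vimentin (ENSG00000026025, chromosome 10, 17228259 to 17237593), fell 1.13-fold. Its level was 1650 ± 45.9 CPM in parental and 1458 ± 30.8 CPM in knockout cells (SD, n = 3 each). The log2 fold change was -0.18 (SE 0.03), with an adjusted p of 2.85e-06 by edgeR. All 3 knockout libraries lay below all 3 parental libraries, and the exact permutation test gave p = 0.1, the smallest possible.

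**Figure D1:**
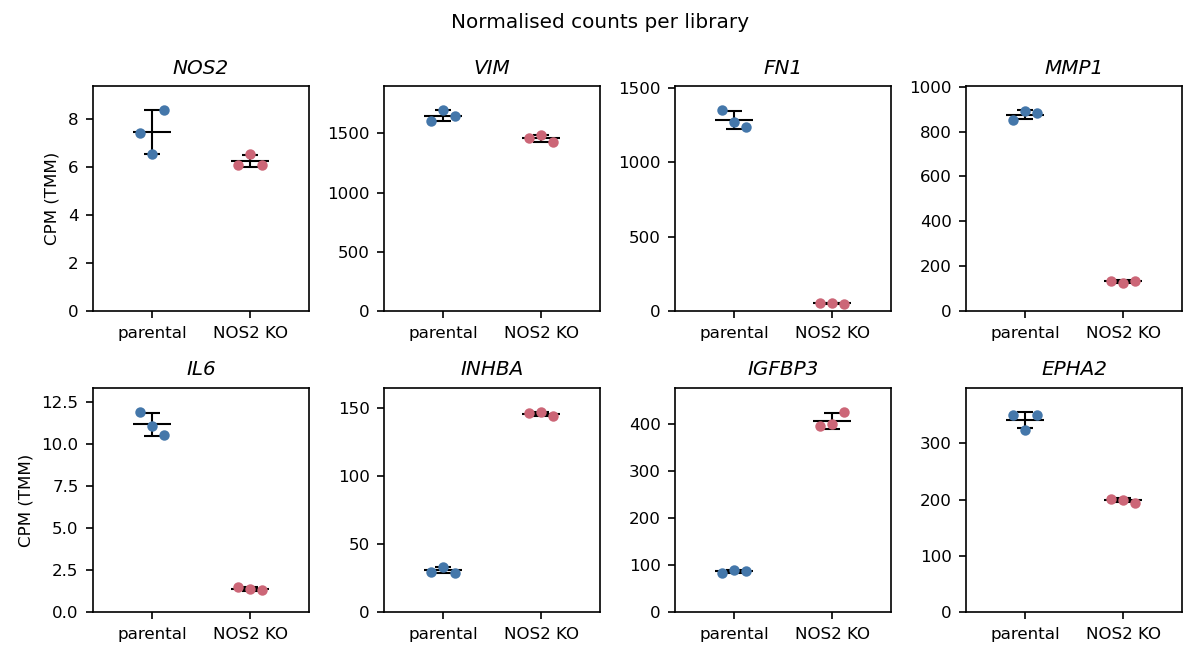
TMM-normalised CPM (vertical axes, starting at 0) of 8 genes in each library of the parental and NOS2 knockout lines. Points are libraries, long bars are means and error bars are the SD over 3 libraries. FN1 lies at 1284 ± 59.2 CPM in parental and 49.9 ± 4.78 CPM in knockout libraries, while VIM lies at 1650 ± 45.9 and 1458 ± 30.8 CPM.

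FN1, MMP1 and IL6 fell and INHBA and IGFBP3 rose by more than 4-fold. FN1, the gene of fibronectin, fell 25.8-fold from 1284 ± 59.2 to 49.9 ± 4.78 CPM (SD, n = 3 each), with a log2 fold change of -4.69 (SE 0.06) and an adjusted p of 2.32e-14. MMP1, an interstitial collagenase, fell 6.66-fold from 875 ± 20.5 to 131 ± 4.84 CPM. IL6, an inflammatory cytokine, fell 7.92-fold from 11.2 ± 0.693 to 1.41 ± 0.113 CPM. INHBA, which encodes a subunit of activin, rose 4.74-fold from 30.8 ± 2.23 to 146 ± 1.47 CPM, and IGFBP3, which binds insulin-like growth factors, rose 4.65-fold from 87.4 ± 2.84 to 407 ± 16.7 CPM.

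Of 16259 genes tested, 6197 (38.1%) changed at an adjusted p under 0.05, of which 3077 rose and 3120 fell. Most differences were small, with a median absolute log2 fold change of 0.27. Groups did not overlap in 46.6% of tested genes, against 10% by chance. At least 2-fold changes were found in 476 genes (2.93%), of which 235 rose and 241 fell. When the test itself was made against a 2-fold change (glmTreat), 148 genes passed, of which 71 rose and 77 fell. With a filter of 1 CPM in 3 libraries the count of 2-fold changes was 288.

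The 10 highest fold changes that met the rule were in SVEP1 (log2 fold change 5.27), LSAMP (4.32), HOXB13 (2.73), DAW1 (2.71), GDF6 (2.64), ANKRD37 (2.49), ANO2 (2.37), INHBA (2.24), RUNX2 (2.23) and IGFBP3 (2.22). SVEP1, an extracellular matrix protein, rose from 0.207 ± 0.101 to 8.26 ± 0.33 CPM, and LSAMP, a cell adhesion molecule, rose from 0.514 ± 0.0214 to 10.4 ± 0.173 CPM. HOXB13 and RUNX2 encode transcription factors and GDF6 a ligand of the BMP family. The 10 lowest were in NEURL1 (-4.77), FN1 (-4.69), GALC (-4.33), TMEM178B (-3.02), IL6 (-2.98), MMP1 (-2.74), KISS1 (-2.41), TFAP2A (-2.41), ZNF699 (-2.37) and L1CAM (-2.28). NEURL1, a ubiquitin ligase, fell from 12.5 ± 0.945 to 0.447 ± 0.184 CPM. GALC, a lysosomal galactosylceramidase, fell from 7.92 ± 0.531 to 0.388 ± 0.0777 CPM. TFAP2A is a transcription factor and L1CAM a cell adhesion molecule. The SEs of these 20 values were 0.03 to 0.20, and their adjusted p values by edgeR were 2.32e-14 or lower.

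On GRCh38, SVEP1 spans 110365251 to 110579880 on chromosome 9, LSAMP 115802363 to 117139389 on chromosome 3, INHBA 41667168 to 41705834 and IGFBP3 45912245 to 45921874 on chromosome 7. NEURL1 spans 103493979 to 103592552 on chromosome 10, FN1 215360440 to 215436172 on chromosome 2, GALC 87837820 to 87993665 on chromosome 14, IL6 22725884 to 22732002 on chromosome 7 and MMP1 102789920 to 102798160 on chromosome 11.

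**Figure D2:**
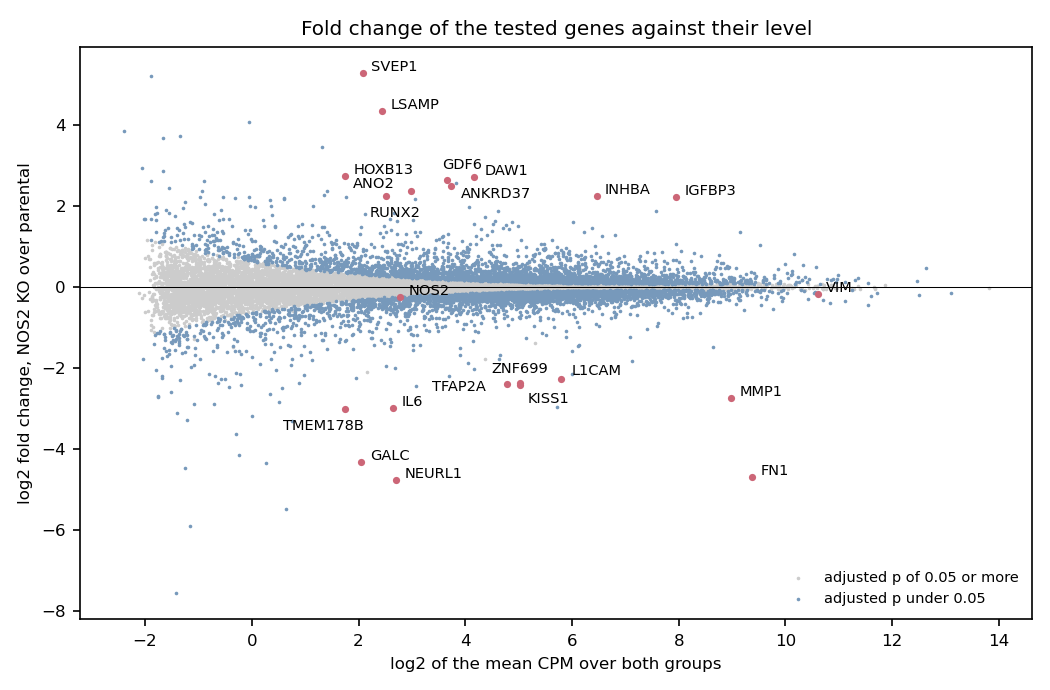
Log2 fold change of knockout over parental (vertical axis) against log2 mean CPM (horizontal axis) for the 16259 tested genes. Grey and blue points are genes with an adjusted p above and below 0.05, and red points are NOS2, VIM and the 20 genes of largest change. FN1 combines a high level with a log2 fold change of -4.69, while NOS2 and VIM lie near 0 at -0.26 and -0.18.

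Mesenchymal markers rose more than they fell, with FN1 and VIM against that direction. Of 26 tested, 14 rose and 3 fell, and 17 changed when adjusted over the list alone. TAGLN, an actin-binding protein of contractile cells, rose by 0.68 on the log2 scale, SPARC, a matrix glycoprotein, by 0.48 and SNAI2, a repressor of epithelial genes, by 0.98. SNAI2 lies in a part of chromosome 8 where neighbouring genes were also higher. The list was called by camera (adjusted p = 0.0183), not with an estimated correlation (adjusted p = 0.486 with an estimated correlation), and without knockout library 1 its adjusted p was 0.0543. Of 22 epithelial markers, 4 rose and 10 fell, and 15 changed when adjusted over the list alone. The keratin genes KRT18 and KRT8 had log2 fold changes of -0.54 and -0.40, the tight junction gene LSR of -0.47 and the splicing regulator ESRP2 of -0.51. Camera gave an adjusted p of 0.0567 for that list, and of 0.0416 when the genes in shifted chromosome regions were left out (0.486 and 0.437 with an estimated correlation). Of 20 genes of intermediate filaments and their partners, 3 rose and 8 fell (12 adjusted over the list alone; camera adjusted p = 0.267). KRT80 rose by 1.51, while LMNA, which encodes lamin A/C, had a log2 fold change of -0.34.

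Adhesion genes fell more than they rose. Of 23 integrins and cadherins, 3 rose and 10 fell, and 13 changed when adjusted over the list alone. The integrin gene ITGA6 and the protocadherin genes PCDH7 and PCDH1 had log2 fold changes of -0.73, -1.30 and -0.91, and CDH2, the gene of N-cadherin, rose by 0.33. This list was called by camera (adjusted p = 0.0346; adjusted p = 0.486 with an estimated correlation). Without parental library 3 or knockout library 3 its adjusted p was 0.0616 or 0.0617, and with the filter of 1 CPM in 3 libraries it was 0.0989. Of 36 genes of extracellular matrix and its proteases, 9 rose and 13 fell (22 adjusted over the list alone; camera adjusted p = 0.256). Besides MMP1, the laminin gene LAMB3, the thrombospondin gene THBS1 and the collagen gene COL13A1 had log2 fold changes of -1.43, -0.96 and -1.44.

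More transcriptional targets of ERK signalling fell than rose. Of 21 tested, 14 fell and 3 rose, and 17 changed when adjusted over the list alone. The receptor gene EPHA2 had a log2 fold change of -0.78, PHLDA1 of -0.86, the phosphatase gene DUSP4 of -2.01 and the AP-1 gene FOSL1 of -0.42. The call by camera (adjusted p = 0.00128) was lost with an estimated correlation (adjusted p = 0.436 with an estimated correlation). NF-kB target cytokines and prostaglandin genes fell more than they rose, with 14 lower and 3 higher of 27 tested and 17 changed when adjusted over the list alone. Besides IL6, the adhesion receptor gene ICAM1 and the cytokine gene IL1B had log2 fold changes of -0.65 and -1.53, while the chemokine gene CCL20 rose by 3.45 from 0.414 ± 0.115 CPM. Camera called this list (adjusted p = 0.0109; adjusted p = 0.486 with an estimated correlation).

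Of 25 antigen presentation genes, 8 fell and 1 rose, and 9 changed when adjusted over the list alone. TAPBP and TAP2, which act in peptide loading, had log2 fold changes of -0.30 and -0.21, HLA-B of -0.18 and CD274, which encodes PD-L1, of -1.31. The call (camera adjusted p = 0.0302; adjusted p = 0.551 with an estimated correlation) was lost without parental library 2 (0.110), knockout library 2 (0.0589) or knockout library 3 (0.0714). Of 37 interferon-stimulated genes, 4 rose and 14 fell (18 adjusted over the list alone; camera adjusted p = 0.197). IFITM3, IFITM2 and IFITM1 had log2 fold changes of -0.66, -0.49 and -1.45, and BST2 rose by 0.48. The IFITM genes lie at 307631 to 327537 on chromosome 11, between its end and a lowered region that starts at 537527.

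More proteasome subunits fell than rose. Of 35 tested, 18 fell and 1 rose, and 20 changed when adjusted over the list alone. PSMD11, PSMD13, PSMA1 and PSMD3 had log2 fold changes of -0.38, -0.39, -0.33 and -0.27. Of the members, 3, among them PSMA1 and PSMD3, lay in chromosome regions where neighbouring genes were shifted, and outside these regions 15 fell and 1 rose. PSMD13, counted as outside, lies at 236546 to 252984 on chromosome 11, before a lowered region that starts at 537527. PSMD11, also counted as outside, starts at 32444261 on chromosome 17, past a lowered region that ends at 31382116. The list was called by camera (adjusted p = 0.00128; adjusted p = 0.599 with an estimated correlation). More genes of G2 and M phase fell than rose, with 19 lower and 4 higher of 41 tested and 23 changed when adjusted over the list alone. TOP2A, AURKB and AURKA, which act in mitosis, had log2 fold changes of -0.30, -0.30 and -0.24, and NDC80 rose by 0.39. TOP2A and AURKB lie in lowered regions of chromosome 17, with medians of -0.24 and -0.28, and outside the shifted regions 17 members fell and 4 rose. NDC80, counted as outside, lies between the end of chromosome 18 and its raised region. Camera gave an adjusted p of 0.0172 (adjusted p = 0.486 with an estimated correlation). Of 37 S phase genes, 10 rose and 10 fell (21 adjusted over the list alone; camera adjusted p = 0.934), and camera and fry differed in sign. TYMS rose by 0.33, MCM4 by 0.28 and POLD1 by 0.21, and RRM1, in the lowered region of chromosome 11 (median -0.27), had a log2 fold change of -0.35. TYMS, like NDC80, lies between the end of chromosome 18 and its raised region. MCM4 ends at 47978160 on chromosome 8, before a raised region that starts at 48917604.

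More genes of the respiratory chain rose than fell. Of the 13 mitochondrially encoded genes tested, 10 rose and 0 fell, and 11 changed when adjusted over the list alone. MT-ND6, MT-ND5, MT-CO2 and MT-ND3 rose by 0.46, 0.38, 0.23 and 0.20 on the log2 scale. The mitochondrial share of all counts was 1.572% to 1.597% in parental and 1.64% to 1.79% in knockout libraries. Camera called the list (adjusted p = 0.0109; adjusted p = 0.599 with an estimated correlation). Of 73 nuclear genes of oxidative phosphorylation, 29 rose and 9 fell, and 43 changed when adjusted over the list alone. NDUFV2, NDUFA9 and UQCRB rose by 0.82, 0.60 and 0.34, and SDHA had a log2 fold change of -0.24. NDUFV2 and NDUFA9 lie in shifted regions of chromosomes 18 and 12, and outside such regions 27 members rose and 8 fell. UQCRB, counted as outside, starts at 96225920 on chromosome 8, past a raised region that ends at 89927888. Over chromosome 8 as a whole, 81.7% of scanned genes were higher, so the members outside the regions are not free of regional shifts. SDHA, counted as outside, lies between the end of chromosome 5 and its lowered region. The call (camera adjusted p = 0.0266; adjusted p = 0.654 with an estimated correlation) was lost without parental library 1 (0.125). Of 76 ribosomal protein genes, 27 rose and 11 fell (39 adjusted over the list alone; camera adjusted p = 0.0607). RPS20 and RPL7 rose by 0.48 and 0.29, and RPS3A and RPS13 had log2 fold changes of -0.45 and -0.24. RPS20, RPL7 and RPS13 were among 8 members in shifted regions. Outside these regions 25 rose and 5 fell, and without the region genes camera gave an adjusted p of 0.0173 (adjusted p = 0.732 with an estimated correlation).

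Of 36 hypoxia and glycolysis genes, 12 rose and 12 fell (24 adjusted over the list alone; camera adjusted p = 0.884), and the mean and fry were positive where the median was negative. The glucose transporter gene SLC2A3 rose 3.02-fold, and on the log2 scale ANKRD37 rose by 2.49, the transcription factor gene BHLHE40 by 0.74 and the glycolytic gene TPI1 by 0.54. SLC2A3 and TPI1 lie in the shifted region of chromosome 12, and 6 of the 36 genes lay in shifted regions. Of 34 genes of the unfolded protein and integrated stress responses, 14 rose and 8 fell (25 adjusted over the list alone; camera adjusted p = 0.197), with rises of 1.03 in ALDH1L2, 1.46 in ATF3, 0.26 in PHGDH and 0.25 in HSP90B1. Of 25 cholesterol synthesis genes, 10 rose and 5 fell (16 adjusted over the list alone; camera adjusted p = 0.235). SQLE, FDFT1 and INSIG1 rose by 0.71, 0.43 and 0.53, and HMGCS1 had a log2 fold change of -0.46. SQLE and FDFT1 lie outside the reported regions of chromosome 8, on which 81.7% of scanned genes were higher. FDFT1 lies in the stretch from 213186 to 15766649 (median 0.25) that was added when regions were extended to chromosome ends. Among 22 immediate early and heat shock genes, 6 rose and 8 fell (14 adjusted over the list alone; camera adjusted p = 0.949), with JUN and JUND up by 0.45 and 0.47 and HSPA1B at -0.27.

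Lists related to nitric oxide and to drug response were not called by camera. Of 23 genes of nitric oxide synthesis and handling, 2 rose and 8 fell (10 adjusted over the list alone; camera adjusted p = 0.235). The arginine transporter gene SLC7A2 rose by 0.42, and PRMT1, an arginine methyltransferase, GCH1, which acts in synthesis of the cofactor tetrahydrobiopterin, and NOS3, the endothelial nitric oxide synthase, had log2 fold changes of -0.18, -0.48 and -0.38. SLC7A2 lies outside the reported regions of chromosome 8, on which 81.7% of scanned genes were higher. NOS3 counts were 440, 463 and 487 in parental and 306, 346 and 388 in knockout libraries. Of 19 genes of drug efflux and platinum transport, 4 rose and 3 fell (6 adjusted over the list alone; camera adjusted p = 0.577). ABCB1, which encodes the efflux pump P-glycoprotein, rose from 6.23 ± 0.434 to 8.62 ± 0.604 CPM, the copper chaperone gene ATOX1 rose by 0.39, and SLC47A1 and SLC31A2 had log2 fold changes of -1.16 and -0.49. Of 32 glutathione and NRF2 genes, 11 rose and 8 fell (20 adjusted over the list alone; camera adjusted p = 0.577). MGST1, which lies in the shifted region of chromosome 12, rose by 0.88 and the ferritin gene FTH1 by 0.29, and TALDO1, in the lowered region of chromosome 11, and TXNRD1 had log2 fold changes of -0.30 and -0.23. Of 41 genes of nucleotide excision and homologous recombination repair, 12 rose and 9 fell (24 adjusted over the list alone; camera adjusted p = 0.723). RAD51AP1 and RAD52 rose by 0.59 and 0.69, and ERCC2 and RAD50 had log2 fold changes of -0.42 and -0.45. RAD51AP1 lies in the shifted region of chromosome 12, where the median was 0.62. RAD52, at 912077 to 990053, lies between the end of that chromosome and the region, which starts at 1565993. It was therefore counted as outside.

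Of 35 apoptosis regulators, 6 rose and 14 fell (20 adjusted over the list alone; camera adjusted p = 0.305), with TNFRSF10D up by 0.42 and CASP4 and PMAIP1 at -0.47 and -0.53. Of 24 p53 targets, 5 rose and 9 fell (14 adjusted over the list alone; camera adjusted p = 0.305). CDKN1A, the gene of the cell cycle inhibitor p21, had a log2 fold change of -0.71 and PLK2 of -0.31, and TIGAR, which lies in the shifted region of chromosome 12 (median 0.62), rose by 0.50. Of 13 stem cell markers, 3 rose and 6 fell (10 adjusted over the list alone; camera adjusted p = 0.283), with ITGA6, CD44, SOX9 and ALDH1A3 at -0.73, -0.31, -0.98 and -0.61. Of 13 Mullerian and ovarian carcinoma markers, 7 rose and 2 fell (9 adjusted over the list alone; camera adjusted p = 0.0989, and 0.0250 without the genes in shifted regions). With an estimated correlation these were 0.486 and 0.429. MSLN, PAX8 and HOXA10 rose by 0.30, 0.53 and 0.77, and WT1 had a log2 fold change of -0.79.

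Genes of the lists for other signalling pathways went both ways. Of 27 TGF-beta and SMAD targets, 13 rose and 6 fell (21 adjusted over the list alone; camera adjusted p = 0.106), with INHBA, PMEPA1 and TAGLN up by 2.24, 1.61 and 0.68 and THBS1 at -0.96. Of 25 YAP and TEAD targets, 6 rose and 11 fell (17 adjusted over the list alone; camera adjusted p = 0.412), with IGFBP3 up by 2.22 and ANKRD1, CAVIN2 and MYOF at -1.48, -1.88 and -0.74. Of 17 WNT targets, 2 rose and 7 fell (10 adjusted over the list alone; camera adjusted p = 0.0607), with the WNT antagonist gene DKK1 at -1.23, CCND1 at -0.25, NKD2 at -0.71 and NOTUM at -1.65. NKD2 lies in the lowered region of chromosome 5 (median -0.31). The NOTCH list of 15 tested genes holds receptors and ligands of the pathway besides its targets. Of these 15, 3 rose and 4 fell, with 7 changed when adjusted over the list alone and a camera adjusted p of 0.847. The targets HEY1, HES4 and NRARP rose by 1.07, 0.27 and 0.29. The ligand genes JAG2 and JAG1 had log2 fold changes of -0.26 and -0.33, and the receptor genes NOTCH3 and NOTCH1 of -0.51 and -0.45. HEY1 lies in a raised region of chromosome 8 (median 0.26). The NOTCH list had a negative median and a positive mean.

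Camera called none of the lists of leukocyte, endothelial, fibroblast and mesothelial markers. Of 20 leukocyte markers, 0 rose and 1 fell, and 0 changed when adjusted over the list alone (camera adjusted p = 0.821). All of these had mean levels above the detection floor in both lines. Parental and knockout levels were 18.3 and 18.2 CPM for LAPTM5, 10.2 and 10.7 for PTPRC, and 5.40 and 4.89 for CD3E. LYZ was highest, at 61.7 CPM in parental libraries, with a log2 fold change of -0.22. NOS2, at 7.46 and 6.26 CPM, lay within this range. Whether such reads, or the NOS2 reads of the knockout libraries, came from OVCAR8 cells was not tested. Of 11 endothelial markers, 0 rose and 3 fell (5 adjusted over the list alone; camera adjusted p = 0.542), with TIE1, ROBO4 and FLT1 at -1.39, -0.71 and -1.30. Without parental library 3 the adjusted p was 0.0550 for ROBO4 and 0.114 for FLT1, and without knockout library 3 it was 0.0507 for FLT1. Of 8 fibroblast and mesothelial markers, 1 rose and 2 fell (4 adjusted over the list alone; camera adjusted p = 0.934), with PDPN up by 1.42 and BNC1 and LRRN4 at -1.12 and -0.44. Of the 35 lists, camera called 10, of which 3 rose and 7 fell, and 0 were called with an estimated correlation, while fry called 24.

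**Figure D3:**
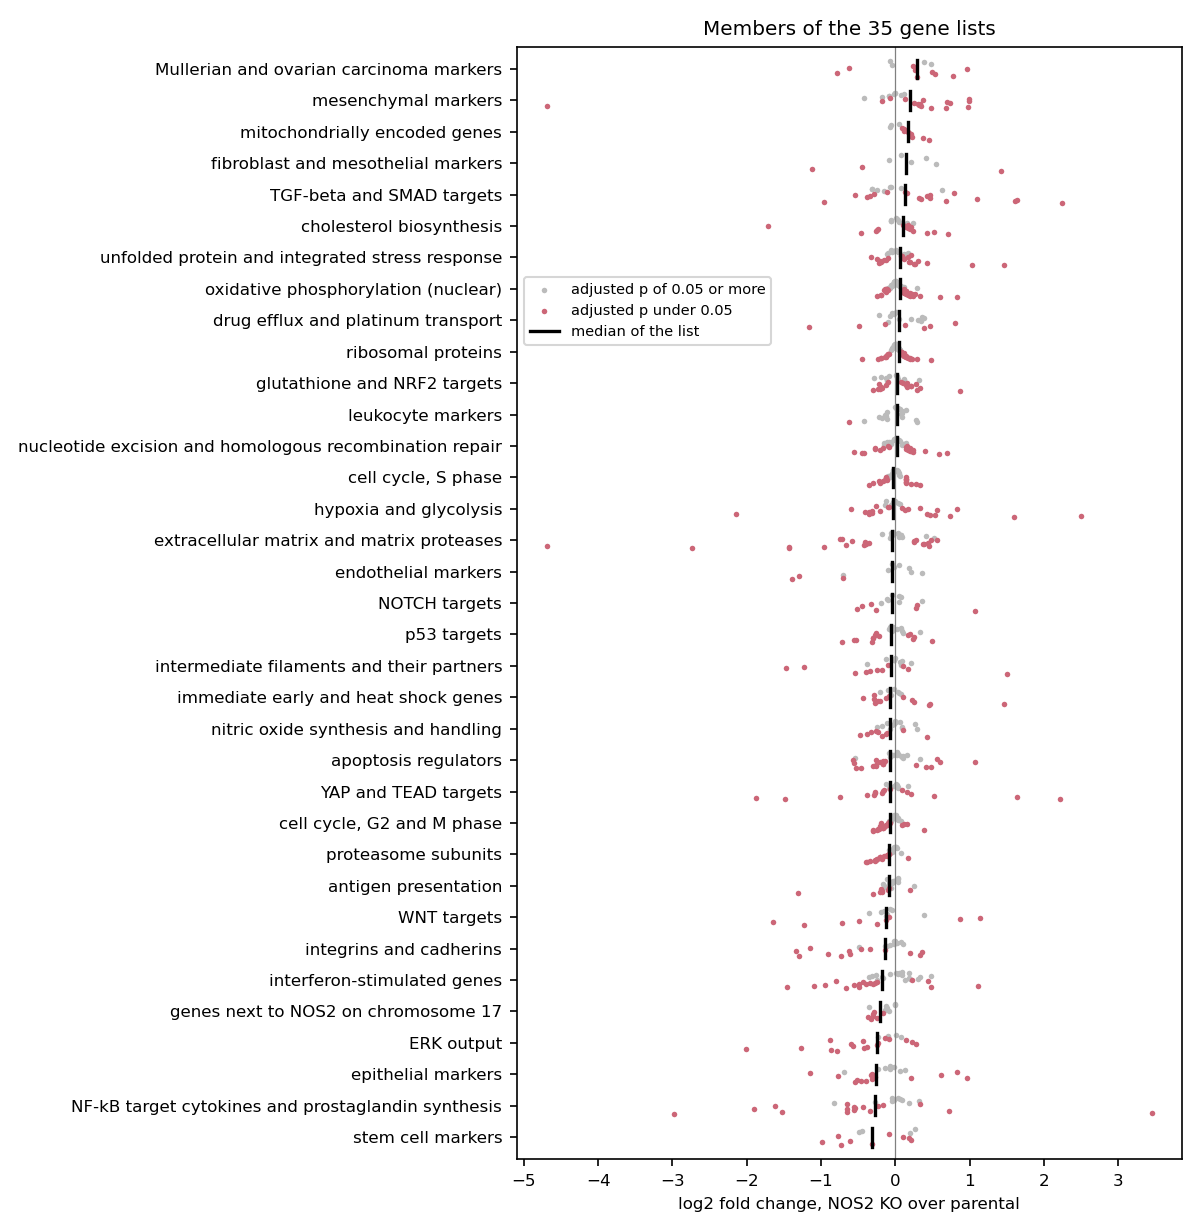
Log2 fold change of knockout over parental (horizontal axis) for each tested member of the 35 lists, sorted by list median. Points are genes, red for an adjusted p under 0.05 and grey otherwise, and vertical bars are list medians. FN1 stands apart at -4.69 in the lists that hold it, and proteasome subunits lie close to 0 with 18 of 35 lower.

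Changes in neighbouring genes were shared over long stretches of chromosomes, which was examined after the data had been seen. The strongest were on chromosome 12, from 1565993 to 40106089, where 176 genes had a median log2 fold change of 0.62 and 95.5% were higher in knockout cells, and on chromosome 18, from 3593732 to 23260467, where 50 genes had a median of 0.62 and 94.0% were higher. Chromosome 12 holds the abundant glycolytic gene TPI1 there. Higher medians of 0.25, 0.26 and 0.27 were found on chromosome 8 from 48917604 to 63039171 and from 66628487 to 89927888, and on chromosome 10 from 42782801 to 47484158. Lower medians were found on chromosome 5 from 892643 to 10249897 (-0.31), on chromosome 11 from 537527 to 32105755 (-0.27), and on chromosome 17 from 4833388 to 9729691 (-0.28), from 28724348 to 31382116 (-0.22) and from 36544888 to 42683917 (-0.24). Together the 10 regions held 738 of 13715 scanned genes, of which 75.6% changed, against 40.9% of the others. The regions were drawn from these same fold changes, so a higher share inside them was built in. They held 558 of the 5871 changed genes that were scanned (9.50%). The number of regions depended on how their ends were drawn, and was 13 or 18 under the other boundary rules tried. Extending regions to chromosome ends added the end of chromosome 4 from 181874438 to 189963204, with 29 genes and a median of 0.56, and parts of chromosomes 8 and 10. It also lengthened reported regions, and gave 886 genes in all against 738. SDHA, IFITM1 to IFITM3, PSMD13, RAD52, TYMS and NDC80 lie between a chromosome end and the start of a reported region, and were counted as outside. Chromosomes taken as a whole also differed. The share of scanned genes that were higher was 19.5% on chromosome 17, 30.3% on 14 and 31.4% on 5. It was 81.7% on chromosome 8, 71.2% on 18 and 70.1% on 12.

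**Figure D4:**
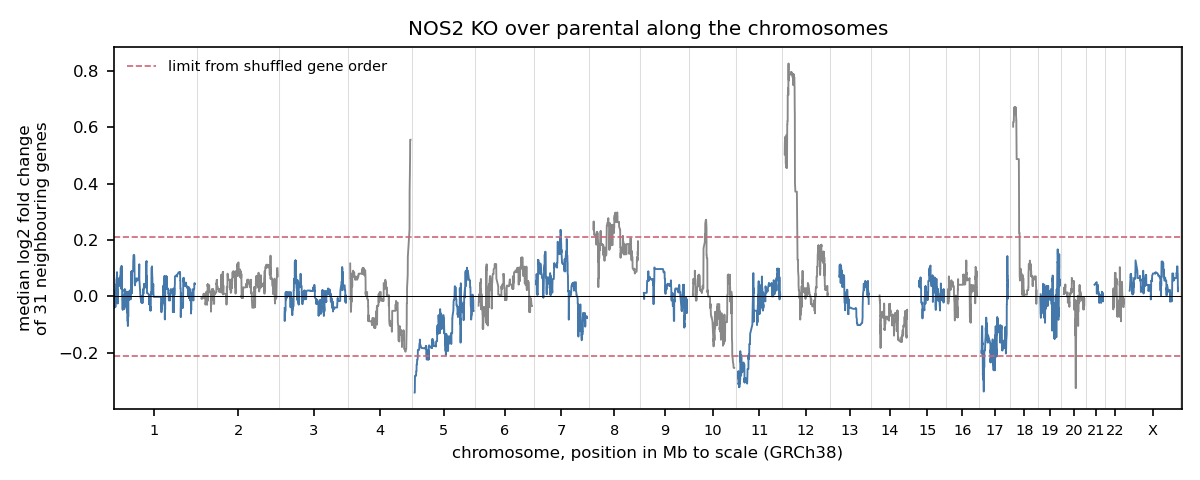
Median log2 fold change of 31 neighbouring genes (vertical axis) along chromosomes 1 to 22 and X (horizontal axis, position to scale on GRCh38). Lines are window medians, and dashed lines mark the limit of 0.212 from shuffled gene order. Windows rise highest on chromosomes 12 and 18 and are mostly below 0 on chromosome 17.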

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

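The GC and length offset and the removal of genes in shifted regions were chosen after seeing the data. Against 6197 changed genes, the other scalings gave 6192 to 6197, no count filter 5840, the filter of 1 CPM in 3 libraries 6048, limma-voom 6139, the GC and length offset 6620 and DESeq2 5102, of which 5092 were shared. Against 476 genes changed 2-fold, no count filter gave 604, of which 453 were shared, and DESeq2 421. The changed genes numbered 5271 to 5878, and those changed 2-fold 476 to 529, when each library was left out. VIM kept its call under the scalings, filters, replicate block, DESeq2, limma-voom, the GC and length offset and each left-out library, with log2 fold changes of -0.20 to -0.16 over left-out libraries. The NOS2 transcript did not: its log2 fold change was -0.26 (adjusted p 0.0542) with no count filter, -0.26 (0.122) with DESeq2, -0.25 (0.0543) with limma-voom and -0.22 (0.0653) with the added GC and length offset. Over left-out libraries it was -0.34 to -0.16, with adjusted p 0.0113 to 0.281, and the call was kept only without parental library 2. The cause was not tested. The genes changed at least 2-fold numbered 288 with a filter of 1 CPM in 3 libraries, which tests fewer genes, and 148 with glmTreat, which tests against a 2-fold change itself. The lists called numbered 0 with an estimated correlation and 24 with fry, which asks a different question of each list, and 7 to 10 over left-out libraries. The hypoxia and glycolysis list reversed direction under fry (adjusted p 0.0108), and the cause was not tested. Without the genes in shifted regions, added later, 5585 genes and 13 lists were called, the 3 added lists being ribosomal proteins (adjusted p 0.0173), Mullerian markers (0.0250) and epithelial markers (0.0416), none of which passed with an estimated correlation (0.732, 0.429 and 0.437). Among 142 named genes besides NOS2 and VIM, calls of 3 were lost in 8 of 2128 comparisons. Replicate numbers did not pair the libraries. In a check of parental against knockout libraries, same-numbered libraries had correlations of 0.07, -0.13 and -0.11, and not every library correlated best with its own number. These are not correlations of levels, which were 0.990 to 0.991 between groups. With the replicate block 6160 genes, 473 genes at 2-fold and 11 lists were called, the added list being the epithelial markers (adjusted p 0.0423, and 0.659 with an estimated correlation).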

Other observations

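The tests of shared shifts with chromosome neighbours or closest genes, of held-out genes, of gene order, of pseudogenes and of single swapped labels were chosen after the result was seen. The test of GC content and length and the splits of the libraries were set before theirs were seen.

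Some other genes changed at least 2-fold, and were picked after their values were seen. GREM1, a BMP antagonist, had a log2 fold change of -1.59 (SE 0.06), and GAS6, a ligand of the AXL receptor, of -1.47, from 102 ± 3.48 to 36.8 ± 1.27 CPM. SERPINB2 was at -2.20 and ALDH2, the mitochondrial aldehyde dehydrogenase, at -1.35. FGF2, a fibroblast growth factor, rose by 1.01, from 57.6 ± 0.531 to 116 ± 3.43 CPM, SCD, which desaturates fatty acids, by 1.06, from 161 ± 5.33 to 336 ± 7.38 CPM, TGFB2 by 1.63, NFIB by 1.71 and WNT7B by 2.26. TERT, the catalytic subunit of telomerase, was at -1.19, from 5.12 ± 0.923 to 2.27 ± 0.254 CPM, and lies in the lowered region of chromosome 5. Among genes changed at least 2-fold, 25 antisense and 18 lincRNA genes rose and 17 of each kind fell.

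The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 6197 changed genes, 476 at 2-fold and 10 lists, and the highest of the others gave 0, 0 and 4. Every other split mixes parental and knockout libraries, so the difference between the lines adds to the spread within its groups. Low counts of changed genes there were likely beforehand, and the contrast with the real split is no independent support. In each case 1 of the splits, the real one, gave a result as large.

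The first pattern is the shift of whole chromosome regions. In shuffled gene order the largest window median was 0.254, against 0.825 observed, and 0 of 1000 shuffles reached it. A GC and length offset left a median of 97.6% of the regional shifts. When regions were drawn afresh from every other gene, 90.1% of the 392 held-out genes in them moved in the found direction, but 3 of these 10 regions lay outside the reported ones, and the reported regions of chromosomes 5 and 10 were not found. A difference in DNA copy number between the lines and shared regulation of neighbouring genes both predict that neighbours move together, and DNA was not measured, so both stay open, as does a difference between clones that has nothing to do with NOS2.

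The second pattern is the NOS2 transcript. Of its 30 nearest tested genes, 27 had log2 fold changes below 0 and 11 lay below NOS2, so its decrease may be one shared with its neighbours. NOS2 pseudogenes held at most 0.712% of the NOS2 count. Reads of pseudogenes that were assigned to NOS2 would be missing from these counts, so they cannot decide whether such reads contributed. The lowest correlation within a group, 0.997, lay above the highest between groups, 0.991, which argues against a single swapped library. An exchange of the whole groups is not checked by this transcript.

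The third pattern is the 20 genes of largest change. The median of the 30 nearest tested genes reached at most 21.1% of the own change, so these genes changed by more than their whole neighbourhood. ANKRD37 and ANO2 had neighbour medians of 0.53 and 0.50. The genes were picked for large changes, and no window median was beyond 0.825. A neighbour median near the own change could therefore hardly occur, and the comparison is no independent test. A shift shared with a few adjoining genes stays open: of the 20 genes, 10 had at least 1 of their 4 closest tested genes changed 2-fold the same way. Of all tested genes, 2.93% changed at least 2-fold. INHBA, IL6 and TFAP2A, which are among the 10, have an antisense gene (INHBA-AS1, IL6-AS1 or TFAP2A-AS1) among their closest genes. With the strand setting unknown, reads of overlapping genes cannot be told apart. For ZNF699, 3 of the 30 nearest genes fell further, and for DAW1 1 rose further. Whether these changes follow from the loss of NOS2 or from differences between the parental and the knockout line that arose separately stays open, since the labels name only 1 knockout line.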
